A study of Homo sapiens with 40 samples.

How the data were processed

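Naive B cells of 6 donors, taken from peripheral blood by depleting other cells with magnetic beads, were cultured for 6 h with soluble CD40 ligand (sCD40L) at 2.5 µg/ml or mock-treated, per the labels. CD40 is the receptor on B cells through which helper T cells, which carry CD40 ligand, drive B cell activation. Total RNA was extracted in 96-well plates, amplified as cDNA with a whole-transcriptome kit for small amounts of RNA, tagged with biotin and hybridised to oligonucleotide arrays, per the labels' protocols. The table holds 40 arrays, 22 of mock-treated and 18 of sCD40L-treated cells, with 2 to 4 arrays for each donor and treatment. The labels number these repeats, and whether they came from separate cultures is not given in the sources used here.

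The deposited values are on a log2 scale, 1 column per array and 1 row per probe set. RMA, which subtracts background, equalises the distributions of the arrays and summarises the probes of each set, is named in the submitters' processing notes. Its version and settings are not given in the sources used here. RMA compresses differences of dim probe sets towards 0, so that fold changes of weakly expressed genes are understated. The array medians lay between 5.80 and 5.85 and the 75th percentiles between 7.25 and 7.42. For arrays, the number of arrays and donors limits the precision, and no count stands behind a value.

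The table held 54715 probe sets, of which 102 were controls of the array. A table of the array's annotation gave 1 gene symbol for 40920 probe sets and several for 864, and 12931 probe sets had no row in it. Symbols were set against the current human RefSeq gene table through the gene identifier, which matched 40864 of the probe sets with 1 symbol, and 0 symbols changed. Probe sets with several symbols or none were tested separately and named no gene. Genes of the Y chromosome and the X inactivation transcript were left out, as the data come from people. Where a gene had several probe sets, which was so for 10536 genes, the one with the highest mean over the 40 arrays stood for it, and 19737 genes were tested. The dimmest and brightest of the control probe sets designed to match no transcript had means of 2.33 and 5.37 on the log2 scale. In 6440 genes both treatment means lay at or below the brighter of these. Where a single treatment mean did, the log2 change is given as measured, with a fold of at least the other mean over that control.

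The donor was the replicate. Arrays of one donor and treatment were averaged, and the 12 means were fitted in R 4.3.3 with limma 3.58.1, with donor as a block and treatment as the term tested (lmFit and eBayes, 2-sided). The Benjamini-Hochberg adjustment ran over the 19737 genes, with a threshold of 0.05 on the adjusted p. A change of 1 on the log2 scale, which is 2-fold, defined the larger changes. Changes are sCD40L minus mock with the standard error (SE) of the fit, and levels are means ± SD over 6 donors. The pairing comes from the labels, which name the donor of each array. Deviations of a donor's mock and sCD40L means from their group means correlated across genes with r from 0.17 to 0.34 in the 6 donors, against a median of -0.05 between different donors.

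Gene lists were written before the data were examined, as were the grouping of the arrays, the tests, the rule for the genes to name and the alternative settings. There were 32 lists with 610 distinct genes, of which 40 have no row here and were not analysed here. They cover NF-κB members and feedback regulators, signalling close to CD40, activation surface molecules, cytokines and chemokines, survival and apoptosis, quiescence and homing, naive B cell identity, B cell receptor signalling, fate-determining transcription factors and MHC class I and II. Others hold S to M phase genes, G1 progression, ribosome biogenesis, glycolysis, sterol synthesis, immediate early genes, type I interferon-stimulated genes, the interferon gamma and IRF1 axis, the unfolded protein and integrated stress response, heat shock, p53 targets, ribosomal proteins, oxidative phosphorylation and housekeeping genes. The remaining lists are markers of T cells, NK cells, monocytes, dendritic cells, platelets, erythroid cells, and memory B and plasma cells. Each list was tested with limma's camera, which compares its genes with all others, at a preset correlation of 0.01, and again with the correlation estimated from the data. fry, which asks whether the genes move one way on balance, and an exact sign-flip permutation over the donors stood beside it. With 6 donors the smallest 2-sided p of that permutation is 0.03125. A further 7 lists were written after the table of all genes had been seen, of which 1 is not reported here.

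Named genes were the 12 with the largest positive and the 12 with the largest negative change among those past the threshold with 1 direction in all 6 donors. From each list came at most 2 rising and 2 falling members with the largest changes past the threshold, or, where none passed, the member with the largest change. CD40, NFKBIA, MYC and CD69 were always included, and the ligand's gene was not analysed here. The 5 genes with the smallest p for a difference between donors completed the 111 genes. A further 45 genes were named after their values had been seen. Differences between donors were tested with limma's moderated F test of the 5 donor-by-treatment terms on the 40 arrays as separate observations, so its p-values measure the spread between repeats, which may be technical. Shares of variance were sums of squares over all genes.

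Each step was tested on simulated data made from the real means and spreads of the 19737 genes. For the comparison of sCD40L with mock, 200 genes were given known changes. Of 50 genes per size, 2.0% were recovered at a log2 change of 0.25, 68.0% at 0.5 and 100.0% at 1 and at 2, with 6.25% of the calls among unchanged genes. There were 144 calls, against 3625 in the real data, so the adjustment was stricter in the simulation. The shares recovered at small changes therefore do not carry over to the real comparison, where they are likely to be higher. Without any changed gene there were 0 calls. For the lists, 3 of 3 lists moved by 0.3 were called and 0 of 29 others. Simulated genes were drawn independently, so this does not show how the preset correlation serves lists of correlated genes. For differences between donors, 90.5% of 200 genes whose change varied with an SD of 1 were recovered.

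Alternative settings were another quantile normalization, subtraction of array medians, removal of the dimmest 40% of genes, the mean of all probe sets of a gene or a test of each of them, medians of repeats, the 40 arrays as observations with donor as a block and with an added random block, a trend and robust prior, no donor block, a block of donor and repeat number, a paired statistic without moderation, and leaving out each donor or each array. Chosen after seeing the data were the removal of arrays with a lower brightness ceiling, the restriction to genes brighter than the nonspecific controls and a fit with measures of array quality. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.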

Results

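Transcript levels in human naive B cells of 6 donors were measured on 40 arrays after 6 h with sCD40L (18 arrays) or mock treatment (22 arrays), to ask what engagement of CD40 alone changes in these cells. Arrays of one donor and treatment correlated with a median r of 0.978 across genes, which are not independent replicates. The median was 0.976 between donors of one treatment and 0.971 between treatments of one donor, so these values hardly tell repeats from other arrays. Treatment accounted for 15.1% of the variance over all genes, donor for 17.9% and their interaction for 10.4%, and the remaining 56.4% lay between repeat arrays. These are raw shares, with 1 term for treatment, 5 for the interaction and 28 residual degrees of freedom between repeats. Shares with more terms take in more of the spread between repeats. They therefore do not rank donor above treatment, nor do they show a response that differs between donors. The first principal component, with 16.4% of the variance, separated all arrays by treatment, from 13.8 to 27.6 after sCD40L and from -24.6 to -4.90 after mock treatment. Control probe sets for RNA quality did not separate the treatments. The 3' minus 5' difference of the GAPDH controls was 0.10 lower after sCD40L (SD 0.14, n = 6 donors, exact sign-flip permutation p = 0.219), and that of the ACTB controls differed by 0.005 (SD 0.221, exact permutation p = 0.906). On 3 arrays, 1 mock and 2 sCD40L, the brightest control probe set lay more than 0.5 log2 units below that of the median array.

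**Figure D1:**
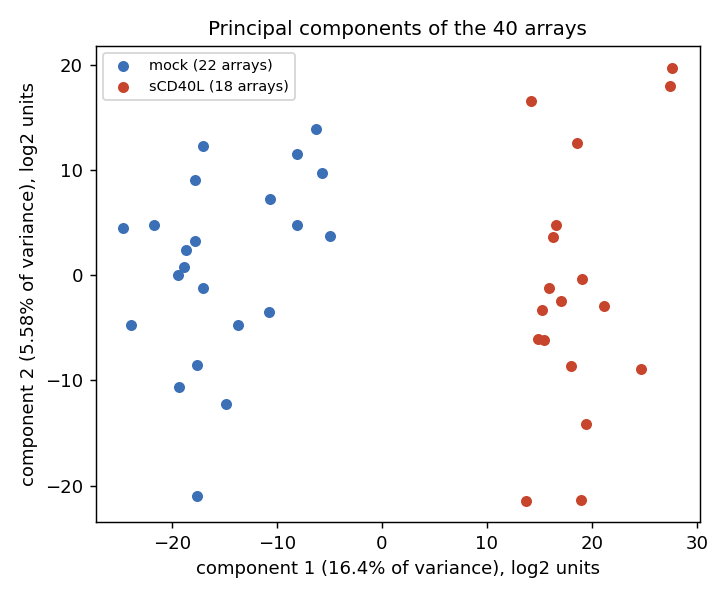
Scores of the 40 arrays on the first 2 principal components of 19737 genes (log2 units), with 1 point per array, mock-treated in blue and sCD40L in red. Component 1 (16.4% of the variance) holds the sCD40L arrays from 13.8 to 27.6 and the mock arrays from -24.6 to -4.90.

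By the brightest probe set of each gene, sCD40L raised the costimulatory ligand CD86, the chemokine CCL22 and the death receptor FAS more than other genes. The G1 kinase CDK6 rose too, and the chemokine receptor CCR6 and S1PR1, the receptor that guides lymphocytes out of lymphoid organs, fell. CD86 went from 5.36 ± 0.52 to 8.21 ± 0.32 (SD, n = 6 donors), a log2 change of 2.85 (SE 0.09, limma adjusted p = 2.81e-09), and was higher in 6 of 6 donors. Its mock mean was not above the brightest nonspecific control (5.37), against which CD86 was at least 7.19-fold higher. CCL22 rose 3.79-fold (log2 change 1.92, SE 0.09), FAS 3.77-fold (1.91, SE 0.12) and CDK6 3.29-fold (1.72, SE 0.10). Dimmer probe sets of TRAF1 (2.43), FAS (2.15) and CDK6 (1.98) rose more than the brightest one, while other probe sets of FAS and CDK6 rose less. CCR6 fell from 8.37 ± 0.34 to 6.53 ± 0.52, a log2 change of -1.85 (SE 0.11), and S1PR1 from 9.74 ± 0.15 to 8.38 ± 0.27, a change of -1.36 (SE 0.08). In all, 3625 of 19737 genes (18.4%) passed the threshold, 1790 higher and 1835 lower, and the median absolute log2 change among them was 0.39.

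Changes of 2-fold or more were seen in 53 genes that rose and 71 that fell, and in 85 and 123 when every probe set of a gene was tested. The other genes among the 12 largest rises were NIBAN1 (log2 change 1.71), FAM241A (1.62), the CD40 adaptor TRAF1 (1.57), MREG (1.52, in 1 of its 2 probe sets), the kinase CAMKK2 (1.46), the export pump ABCC4 (1.43), the transporter SLC43A3 (1.43) and the noncoding RNA LINC02912 (1.42). C16orf54 had the largest measured fall, from 7.56 ± 0.53 to 5.32 ± 0.26 (log2 change -2.25, SE 0.17, limma adjusted p = 2.57e-06), followed by the protease FAM111B (-2.06, SE 0.19). TBC1D9 (-1.78), ATOSA (-1.71), the G protein subunit GNB5 (-1.49), TBC1D10C (-1.49), ZCCHC18 (-1.37), the dipeptidase DPEP2 (-1.36) and the potassium channel KCNA3 (-1.35) completed the largest falls with the nucleotide sugar receptor P2RY14 (-1.52). The P2RY14 means, 5.26 and 3.74, were not above the brightest nonspecific control in either treatment. After sCD40L this also held for C16orf54 and for KCNA3 (4.66), which were at least 4.58-fold and 1.56-fold lower when set against that control. These 24 genes moved one way in 6 of 6 donors by the rule that chose them, and so did each further gene named in the gene lists that follow as risen or fallen, unless another number stands beside it. Among all changed genes 2997 (82.7%) had one direction in 6 of 6 donors, against 20.3% of all genes tested and 3.13% by chance. The threshold itself favours genes on which the donors agree, so the first share is no independent evidence. In ABCC4, C16orf54, CDKN1B, IL2RA, MCM4, MREG, NIBAN1 and SDHA 1 donor stood apart from the other 5 in the size of the change. With an unmoderated paired statistic the count of changed genes was 2095 in place of 3625.

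**Figure D2:**
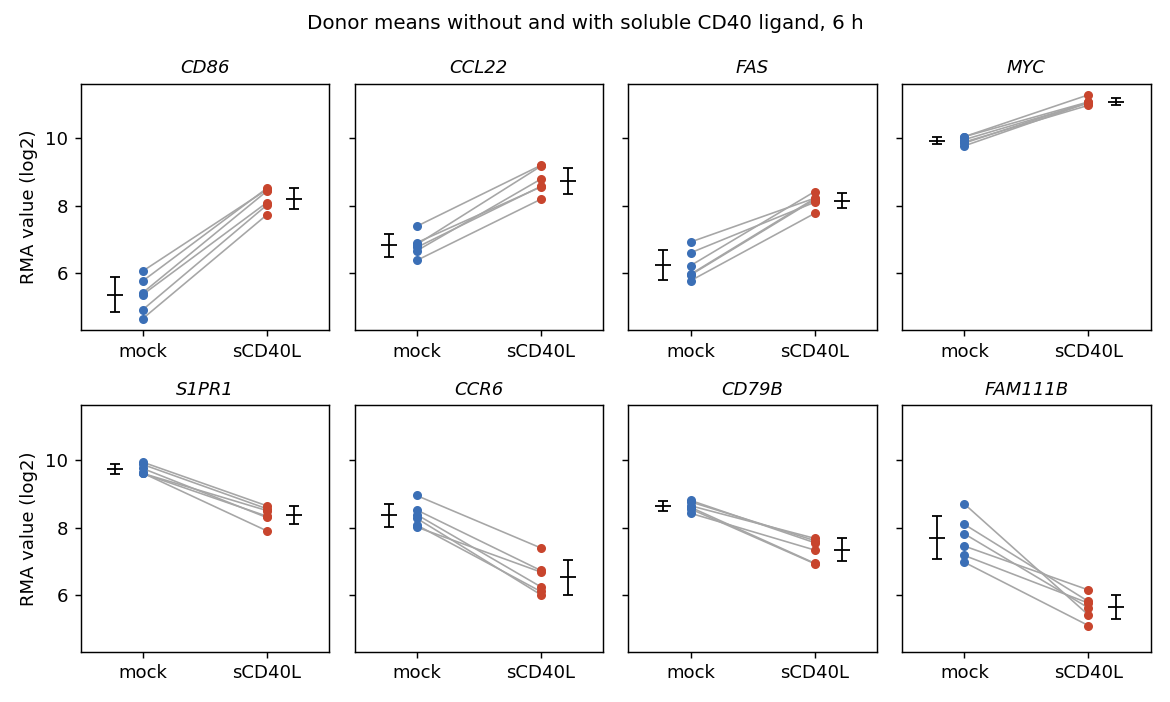
RMA values (log2) of 8 genes, 1 point per donor mean (n = 6), mock in blue and sCD40L in red, with lines joining the 2 values of a donor and black bars for mean ± SD. CD86, CCL22, FAS and MYC rise and S1PR1, CCR6, CD79B and FAM111B fall in 6 of 6 donors, with log2 changes from 2.85 for CD86 to -2.06 for FAM111B.

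Of the 32 gene lists 12 shifted against the other genes (camera, preset correlation), 6 up and 6 down. With an estimated correlation 5 of them held, namely ribosome biogenesis, activation surface molecules, the stress response, B cell receptor signalling and quiescence and homing. In the rising lists the mean change was positive, and in the falling lists negative, in 6 of 6 donors (exact permutation p = 0.03125 for each, the smallest 6 donors allow).

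Ribosome biogenesis genes rose almost without exception. Of 24 measured, 22 were higher and 0 lower, and 23 were higher when adjusted over the list alone, with a mean log2 change of 0.51 ± 0.08 (SD over 6 donors) and a camera adjusted p of 4.7e-19 (0.041 with an estimated correlation). NOP16 (0.94, SE 0.09) and RRS1 (0.86, SE 0.08), both needed for the large ribosomal subunit, led it, although 2 of the 4 NOP16 probe sets did not rise (-0.16 each). MYC, the transcription factor that drives many such genes, rose 2.23-fold (log2 change 1.16, SE 0.07, limma adjusted p = 5.32e-07). The ribosomal proteins themselves showed no such shift. Of 21 measured, limma called 0 over all genes and 0 over the list alone, 0 reached an unadjusted p under 0.05, and the largest change was -0.13 (RPS19).

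Surface molecules of B cell activation formed the list with the largest mean rise, 0.55 ± 0.10. Of 24 measured, 16 were higher and 0 lower (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.87e-11, and 0.041 with an estimated correlation). Besides CD86 and FAS, the interleukin 2 receptor chain IL2RA rose by 1.32 (SE 0.13), and the adhesion molecule ICAM1 (0.95) and the second costimulatory ligand CD80 (0.84), named after their values were seen, were higher as well. CD69, an early activation marker, stood at 9.73 ± 0.28 and 9.79 ± 0.30 (log2 change 0.06, SE 0.07, higher in 3 of 6 donors, limma adjusted p = 0.694). CD40 itself changed by 0.14 (SE 0.07, higher in 6 of 6 donors, adjusted p = 0.172) by its brightest probe set, while its other 3 probe sets rose by 0.22, 0.31 and 0.52.

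NF-κB members and feedback regulators rose by 0.40 ± 0.06 on average, with 12 of 19 higher and 1 lower over all genes and over the list alone (camera adjusted p = 1.9e-07; adjusted p = 0.0530 with an estimated correlation). TRAF1 and the survival gene IER3 (1.21, SE 0.14) led, the inhibitor NFKBIA rose by 0.58 (SE 0.06), and the coactivator BCL3 fell by 0.23 (SE 0.07, a call lost in 6 of 21 other settings). Among genes of signalling close to CD40, TRAF1 and TAB2 (0.31) rose, while the adaptor TRAF5 (-1.05, SE 0.07) and the kinase MAP3K1 (-0.56), with 3 of 17 in all, fell. That list did not shift against the other genes (median 0.01, camera adjusted p = 0.767), and the same 2 rose and 3 fell adjusted over the list alone.

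Of 20 survival and apoptosis genes 7 were higher and 1 lower, over all genes and over the list alone (camera adjusted p = 0.0184; adjusted p = 0.345 with an estimated correlation). The mean, 0.24 ± 0.07, exceeded the median of 0.08, with FAS, which triggers cell death, and the BCL2 family protector BCL2L1 (1.02, SE 0.08) as its largest rises. BCL2L2, another protector of that family, fell by 0.40 (SE 0.08), to a mean not above the brightest nonspecific control. Set against that control it was at least 1.16-fold lower. The shift was lost when genes no brighter than the nonspecific controls were left out. Cytokine and chemokine genes went both ways, with 8 of 28 higher and 4 lower (12 and 5 adjusted over the list alone) and no shift against the other genes (camera adjusted p = 0.103). Their balance was upward by fry (adjusted p = 0.00735), with a mean of 0.13 that was positive in 6 of 6 donors. After CCL22 the largest rise was that of EBI3 (1.16, SE 0.10), a subunit of interleukins 27 and 35, and the largest falls were those of IL24 (-0.96, SE 0.14) and IL16 (-0.91, SE 0.09).

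Stress response genes rose, 9 of 18 with 0 falling (11 adjusted over the list alone), by 0.32 ± 0.05 on average (camera adjusted p = 1.4e-06, and 0.041 with an estimated correlation). The leading members, the metabolic stress sensor SESN2 (0.90, SE 0.08) and asparagine synthetase ASNS (0.90, SE 0.08), are targets of ATF4 that answer amino acid shortage. Of 15 heat shock genes 5 were higher and 1 lower (8 and 1 adjusted over the list alone), a mean of 0.15 ± 0.06 (camera adjusted p = 0.0123; adjusted p = 0.277 with an estimated correlation). The chaperones HSP90AB1 (0.57, SE 0.07) and mitochondrial HSPD1 (0.43, SE 0.07) rose, and the stress-inducible HSPA6 fell by 0.28 (SE 0.08, a call lost in 8 of 21 other settings).

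Genes of quiescence and homing fell by 0.37 ± 0.05 on average. Of 22 measured, 12 were lower and 3 higher over all genes and over the list alone (camera adjusted p = 1.83e-06, and 0.041 with an estimated correlation). After S1PR1, the mRNA-destabilising protein ZFP36L2 fell most (-1.08, SE 0.09), whereas IL7R (0.46, SE 0.15, with 1 donor at 1.47 and the others at most 0.60) and GPR183 (0.33, SE 0.07), a receptor that positions B cells in follicles, rose. The IL7R call was lost in 9 of 21 other settings. B cell receptor signalling genes fell too, 17 of 23 with 2 rising (18 and 3 adjusted over the list alone), by 0.28 ± 0.04 on average (camera adjusted p = 8.91e-07, and 0.041 with an estimated correlation). The receptor chain CD79B went from 8.63 ± 0.14 to 7.34 ± 0.34 (log2 change -1.29, SE 0.10) by its brightest probe set, against -0.23 and -0.03 in the other 2, which were dimmer. The phospholipase PLCG2 fell by 0.68 (SE 0.08) in 1 of its 2 probe sets, while the complement receptor CR2 (1.30, SE 0.10) and the exchange factor VAV3 (0.38, SE 0.08) rose.

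Of 23 naive and pan B cell genes 12 were lower and 5 higher (15 and 5 adjusted over the list alone), a mean of -0.30 ± 0.08 (camera adjusted p = 2.69e-05; adjusted p = 0.198 with an estimated correlation). The immunoglobulin mu chain IGHM fell by 0.94 (SE 0.07), and the B lineage factor PAX5 rose by 0.32 (SE 0.08). Markers of memory B and plasma cells, which bead depletion to naive B cells should remove, fell in 6 of 16 and rose in 1 (7 and 1 adjusted over the list alone). Their mean was -0.20 ± 0.07 but their median -0.03 (camera adjusted p = 0.0498, and adjusted p = 0.198 with an estimated correlation). The joining chain JCHAIN fell from 7.31 ± 0.60 to 6.42 ± 0.94 (log2 change -0.89, SE 0.17), the DNA sensor AIM2 by 0.76 (SE 0.12), and FCRL4 rose by 0.40 (SE 0.09, 5 of 6 donors). The shift of this list was lost in 11 other settings.

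MHC class II genes fell in 6 of 19 with 0 rising, over all genes and over the list alone (mean -0.22 ± 0.09, camera adjusted p = 0.00118; adjusted p = 0.270 with an estimated correlation). The falls were largest in the peptide exchange factors HLA-DMB (-1.08, SE 0.09) and HLA-DMA (-0.85, SE 0.06). Class I genes did not shift against the other genes (camera adjusted p = 0.423; fry adjusted p = 0.0520). Of 18 measured, 3 fell and 1 rose over all genes and over the list alone. Among them were the peptide trimmer ERAP2 (-0.78, SE 0.12), the immunoproteasome subunit PSMB9 (-0.63, SE 0.07) and the proteasome activator PSME2 (0.30, SE 0.06). Type I interferon-stimulated genes fell in 11 of 24 with 0 rising (12 adjusted over the list alone), by 0.27 ± 0.11 on average (camera adjusted p = 8.91e-07; adjusted p = 0.133 with an estimated correlation). The antiviral MX2 (-0.55, SE 0.10, lower in 5 of 6 donors) and the signal transducer IRF9 (-0.54, SE 0.07) fell most. In the list of the interferon gamma and IRF1 axis 3 of 14 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.589; fry, downward, adjusted p = 0.0291). SOCS3 (0.71, SE 0.07) and WARS1 (0.51, SE 0.08) were higher, and GBP4 (-0.74, SE 0.09) and IRF1 (-0.63, SE 0.07) lower.

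**Figure D3:**
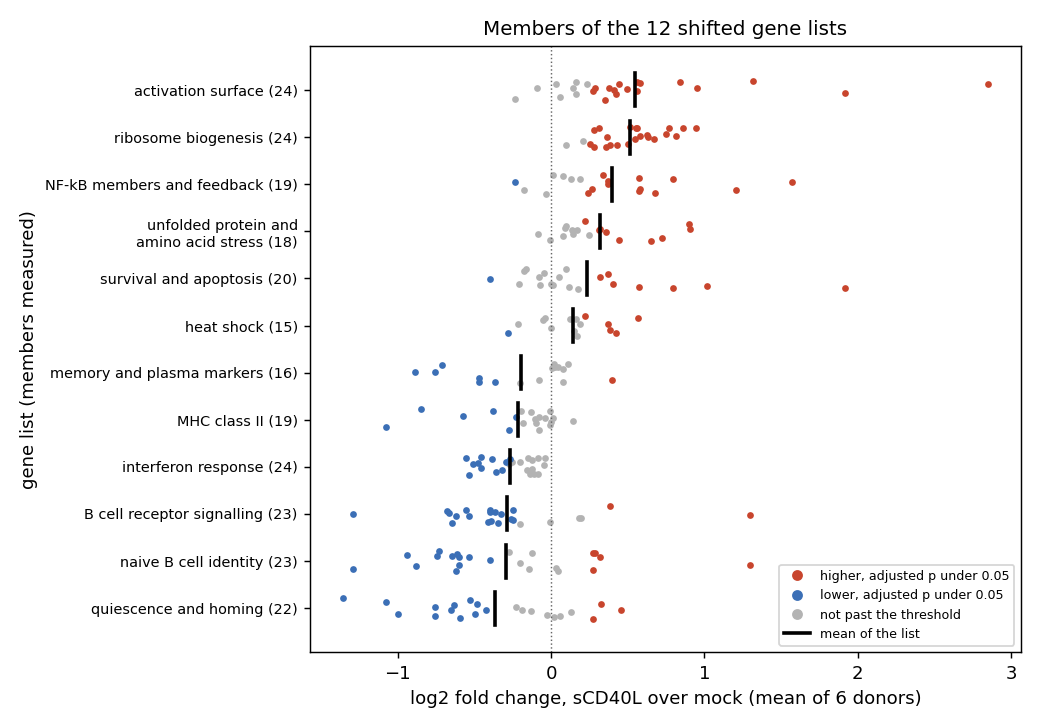
Log2 fold change of each measured member of the 12 shifted lists (mean of 6 donors, sCD40L over mock), with 1 point per gene, red for higher and blue for lower at an adjusted p under 0.05, grey otherwise, and a black bar for the mean of the list. In ribosome biogenesis 22 of 24 members are higher, and in B cell receptor signalling 17 of 23 are lower.

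Genes of G1 progression moved far in both directions. Of 18 measured, 7 rose, led by CDK6 and MYC, and 6 fell. By the brightest probe sets, the cell cycle inhibitor CDKN1B (-0.63, SE 0.08) and CCND3 (-0.44, SE 0.09) led the falls. The other, slightly dimmer CCND3 probe set fell more (-1.32). The counts of rises and falls were the same over the list alone, with no shift against the other genes (camera adjusted p = 0.219). On balance the G1 genes moved up by fry (adjusted p = 2.29e-04), with a mean of 0.19 that was positive in 6 of 6 donors. S to M phase genes changed in 3 of 25 over all genes and over the list alone, MCM4 (0.43, 5 of 6 donors) and PCNA (0.29) upward and MCM5 (-0.40) downward (camera adjusted p = 0.799). The PCNA call was lost in 11 of 21 other settings. Fate-determining transcription factors split likewise, with STAT5A (0.80, SE 0.07) and IRF4 (0.59, SE 0.07) among 9 of 28 that rose and ETS1 (-0.79, SE 0.08) and the germinal centre repressor BCL6 (-0.49, SE 0.08) among 5 that fell, in equal numbers over the list alone (camera adjusted p = 0.547). Of 21 immediate early genes 5 rose, DUSP5 (1.36, SE 0.08) and FOSL1 (1.11, SE 0.12) most, and 2 fell (6 and 5 adjusted over the list alone). Those 2 were EGR3 (-0.62) and NR4A3, which passed in 1 of its probe sets (-0.38, against -0.15 in each of the others). The immediate early list did not shift against the other genes (camera adjusted p = 0.423), while fry called it upward (adjusted p = 0.0246). Of 18 p53 targets 6 rose, with GADD45A (0.98, SE 0.13) after FAS, and 4 fell, TP53INP1 (-1.22, SE 0.09) and SESN1 (-0.59) most (6 and 5 adjusted over the list alone; camera adjusted p = 0.455; fry, upward, adjusted p = 0.0451).

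Glycolysis, sterol synthesis and oxidative phosphorylation did not shift against the other genes at the preset correlation, nor did fry call them. In glycolysis 6 of 19 genes rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.423). HK2 (0.75, SE 0.07) and ENO1 (0.64, SE 0.09) were higher, and ENO2 (-0.47) and PFKFB3 (-0.40) lower. In sterol synthesis 5 of 16 rose and 2 fell over all genes and over the list alone (camera adjusted p = 0.219), CYP51A1 (0.55) and INSIG1 (0.48) against STARD4 (-0.56) and SC5D (-0.52). Of 23 oxidative phosphorylation genes CYC1 (0.30) rose and 3 fell, SDHA (-0.38) and COX4I1 (-0.23, a call lost in 7 of 21 other settings) most, with the same counts over the list alone (camera adjusted p = 0.710). Of 12 housekeeping genes HPRT1 (0.55) and TFRC (0.38, 5 of 6 donors, a call lost in 9 of 21 other settings) rose and SDHA and GAPDH (-0.37, SE 0.07) fell. These counts held over all genes and over the list alone (camera adjusted p = 0.830), and none of these directions turned under either other normalization of the arrays.

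Markers of other blood cells, which the bead depletion should remove, did not shift against the other genes as lists, while fry called the monocyte list upward (adjusted p = 0.0342, mean 0.08, positive in 6 of 6 donors). In the T cell list CD3D, at 6.92 ± 0.16 and 6.67 ± 0.10, was lower (-0.25, 5 of 6 donors, limma adjusted p = 0.0468), 1 of 16, and 0 passed over the list alone (camera adjusted p = 0.547). Among 10 dendritic cell markers CD1C (-0.37, adjusted p = 0.0491) and TCF4 (-0.30, adjusted p = 0.0120), which B cells also express, were lower, likewise over the list alone (camera adjusted p = 0.830). Of 17 monocyte markers SERPINA1 (0.95) and CD163 (0.22) were higher, and 1 over the list alone (camera adjusted p = 0.423). Only 1 of the 4 SERPINA1 probe sets rose, and the calls of CD163, CD3D and CD1C were lost in 16, 11 and 11 of 21 other settings. limma called 0 of 14 NK cell markers (camera adjusted p = 0.630), 0 of 12 platelet markers (0.972) and 0 of 7 erythroid markers (0.739). The counts over the lists alone were 0 too, and 1, 1 and 2 of them had an unadjusted p under 0.05. Their largest changes were those of NKG7 (-0.20), GNG11 (0.21, not above the brightest nonspecific control) and EPB42 (-0.28). NKG7 and EPB42 were not above that control after sCD40L, and their mock means lay 1.12-fold and 1.07-fold above it. Neither change passed the threshold (limma adjusted p = 0.0923 and 0.0931), and neither had one direction in all donors. Means and medians of the lists differed in sign for dendritic cell, erythroid and housekeeping genes, and the small positive mean of the CD40-proximal list went with a camera direction of down.

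How far the response differed between donors was tested gene by gene. The changes of any 2 donors correlated across genes with r from 0.411 to 0.576 (median 0.527), and genes are not independent replicates. In the test of differences between donors 1 gene passed, IL24 (limma adjusted p = 0.00587), whose fall ranged from -1.94 to -0.61 over the donors. At an unadjusted p under 0.05 there were 1183 genes, against 987 by chance. On simulated data this test recovered 90.5% of genes whose change varied between donors with an SD of 1, while the median SD of the change over donors was 0.19, so that smaller differences were not excluded. The next smallest p-values belonged to SEPTIN11 (changes from -0.22 to 1.02), IL2RA (1.02 to 2.18), OSBPL3 (-1.24 to 0.39) and PKIA-AS1 (-0.34 to 1.99), each with an adjusted p of 0.480. The mock mean of PKIA-AS1 was not above the brightest nonspecific control, against which its sCD40L mean was at least 1.37-fold higher. With the mean of a gene's probe sets 3 genes passed, FAM111B, IL24 and NRP2, the last named after the result was seen. Without 1 of the donors limma called 0 genes, with 1095 at an unadjusted p under 0.05.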

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

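The count of genes whose response differed between donors was compared with 100 sets made by permuting the residuals of a fit without such differences, the real data among them. As large a count came up in 5 of the 100, and the highest of the others was 2 against 1 in the real data, so that chance is not excluded for the count. The gene concerned is IL24, with an adjusted p of 0.00587 (limma F test). Its fall was -1.94 in the donor with the largest change and lay between -1.04 and -0.61 in the other 5.

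In 10 of 109 named genes 1 donor's change stood far from the other 5, and chance alone would give about 1 in 20 for independent genes. These genes share the same 6 donors and are not independent, so that rate is no yardstick for the count. IL24 and IL2RA, both among the 10, were named for a small p of a difference between donors, so the share is not independent of how the genes were chosen. The measure is the gap to the nearest donor as a share of the whole range, against its 95% critical value for 6 donors. For IL2RA it was 0.773, with 1 donor at 2.18 and the others between 1.02 and 1.29, and for NIBAN1 it was 0.697, with 1 donor at 2.76 and the next at 1.75. MREG gave 0.712 (2.10 against 1.55) and IL7R 0.630 (1.47 against 0.60), again with 1 donor above the rest. C16orf54 fell by 1.01 in 1 donor and by at least 2.31 in the others, a ratio of 0.748, and SDHA fell less in 1 donor than in the rest, a ratio of 0.692. ABCC4 rose by 0.63 in 1 donor and by at least 1.46 in the others (0.695), and MCM4 was lower in 1 donor, by 0.18 on the log2 scale, and higher by at least 0.45 in the rest (0.735). CDKN1B fell by 1.02 in 1 donor and by 0.63 in the next (0.660). For IL24 the ratio was 0.672.

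Over 32 list means the same measure singled out 3. The naive B cell identity list fell by 0.14 in 1 donor and by 0.30 to 0.35 in the others (ratio 0.763). The list of signalling close to CD40 was lower by 0.16 in 1 donor and between 0.004 and 0.08 in the others (0.683). The heat shock list rose by 0.26 in 1 donor and by at most 0.15 in the others (0.659).

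Probe sets with several gene symbols or none entered no comparison of named genes. Of 13675 such probe sets 2031 changed at a limma adjusted p under the threshold, 14.9%, with 1051 higher and 980 lower and log2 changes from -1.96 to 2.04. They name no gene here.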

How the results depend on the processing

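The settings with measures of array quality, without dim genes by the nonspecific controls and without the arrays of lower ceiling were chosen after seeing the data. The count of changed genes ranged from 2906 without the donor block to 4666 with every probe set tested, except for an unmoderated paired statistic, which gave 2095 (1080 higher, 1015 lower). It estimates each gene's spread from 5 residual degrees of freedom alone. With every probe set tested, 85 genes were at least 2-fold higher and 123 lower, since more probe sets were tried per gene. Of the 3625 genes, 3184 remained called without the 3 arrays of lower ceiling, 3353 among 13103 genes brighter than the nonspecific controls, and 3327 with array quality in the model. Leaving out a donor gave 2912 to 3318 genes and leaving out an array 3213 to 3674. Repeat numbers of one donor did not pair arrays (median r of -0.002 over 17 pairs, from -0.09 to 0.07). With donor and repeat number as a replicate block the count was 3746, and without any block on donor it was 2906, 1481 higher and 1425 lower. Of the named genes past the threshold 18 lost it without the donor block and 5 with donor and repeat number as the block, and neither of these blocks moved a count of genes or lists by over 1.5 times.

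Of the 12 shifted lists 5 held with an estimated correlation, and fry called 18. The exact sign-flip permutation called 0 after adjustment, since 6 donors cannot go below p = 0.03125, which 19 lists reached. Donors left out gave 11 to 12 lists. Memory and plasma cell markers lost their shift in 11 settings and survival genes in 3. The count of genes differing between donors was 3 with the mean of a gene's probe sets (FAM111B, IL24 and NRP2, of which NRP2 was named after the result was seen), and 0 to 1 with a donor left out. At 0, limma found 1095 genes at an unadjusted p under 0.05. As raw shares, treatment explained 20.3% and donor 19.4% of the variance when the dimmest 40% of genes were left out. Those genes carry more noise between arrays, and this cause was not tested. Of 143 named genes past the threshold 106 stayed past it in one direction in every one of the 21 settings that tested them, filters on dim genes having left some out of 2. CD163 (16 settings), PCNA, CD3D and CD1C (11 each) and IL7R, TFRC and PKIA-AS1 (9 each) lost it most often. NIFK-AS1 reversed, to 0.22 with the mean of its probe sets and 0.88 by its most significant one, because its probe sets oppose one another. Signal over background limits dim genes, and 222 changed genes were not above the nonspecific controls in either treatment.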

Other observations

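The gene lists described next, the genes named in them and the test of dendritic cell and monocyte markers, the fit with array quality and the fit without arrays of lower ceiling were chosen only after the table of all genes had been seen. Their p-values therefore describe genes picked for their values and are no independent evidence of a shift. Nucleotide synthesis genes were higher in 11 of 17 and lower in 0 (mean log2 change 0.47 ± 0.13, SD over 6 donors, camera adjusted p over the 7 lists 5.34e-11, and 0.0370 with an estimated correlation), led by CTP synthase CTPS1 (0.99, SE 0.12) and the purine enzyme PFAS (0.86, SE 0.09). Of 19 cytosolic aminoacyl-tRNA synthetases 15 rose, YARS1 and FARSB by 0.64 each, and QARS1 fell by 0.25 (mean 0.38 ± 0.09, camera adjusted p = 2.87e-11, and 0.0478 with an estimated correlation). In serine and folate one-carbon metabolism 6 of 11 rose, among them PSAT1 (1.17, SE 0.12) and the mitochondrial MTHFD2 (1.03, SE 0.07), and the transporter SLC1A4 fell by 0.34 (mean 0.43 ± 0.04, camera adjusted p = 1.06e-05, and 0.0370 with an estimated correlation). The mock mean of PSAT1 was not above the brightest nonspecific control, against which PSAT1 was at least 1.46-fold higher. Mitochondrial ribosomal proteins rose in 10 of 22 with 0 falling (mean 0.24 ± 0.05, camera adjusted p = 3.88e-06, and 0.0370 with an estimated correlation), with MRPL12 (0.72) and MRPL4 (0.71) first. Subunits of RNA polymerases I and III rose in 7 of 14 and fell in 1 (mean 0.30 ± 0.11, camera adjusted p = 2.85e-05; adjusted p = 0.0544 with an estimated correlation), with POLR1G (0.72) and POLR1A (0.71) first.

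Lysosomal genes fell in 6 of 18 and rose in 2 (mean -0.18 ± 0.06, camera adjusted p = 0.00396; adjusted p = 0.0544 with an estimated correlation), with cathepsin B (CTSB, -0.82, SE 0.07) and acid ceramidase (ASAH1, -0.79, SE 0.08) lower and cathepsin C (CTSC, 0.59, SE 0.11) and progranulin (GRN, 0.28) higher. Constant regions of switched immunoglobulins, IGHA1 (-0.71, SE 0.08) and IGHG1 (-0.47, SE 0.08), fell beside IGHM.

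The count of genes changed by sCD40L was compared with exchanges of the treatment within donors. Of the 32 such splits only the real one, 1 split, gave 3625 genes, and the highest of the others gave 0. This is the smallest share that 32 splits can give, so chance is made unlikely but cannot be excluded. At an unadjusted p under 0.05 the real split had 5698 genes and the others at most 3076. Without donor in the model, 100 of the 462 splits of the 12 means were drawn, and 1, the real one, gave 2906 genes. Such splits do not keep the pairs and treat the correlated means of one donor as exchangeable. The highest of the others, 447, left 5 of the 6 means on each side with their own treatment. For the gene lists 1 of the 32 splits within donors, the real one, gave 12, and the highest of the others gave 10. The real split ranked first, but by a small margin and at the smallest share 32 splits allow. Chance is therefore not excluded for that count. The 6 splits nearest to the real one, with the treatment of 1 donor exchanged, gave 9 to 10 lists, and splits with 3 donors exchanged gave at most 1.

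Interferon-stimulated genes were lower after sCD40L, with a list median of -0.26 and a negative median in 6 of 6 donors, though 13 of 24 members did not pass and the shift was not called with an estimated correlation (adjusted p = 0.133). In a fit of the 40 arrays as observations the median change was -0.24. With the 3' to 5' differences and the spread of each array in that fit it was -0.25, which is 104% of it. None of these measures separated the treatments (for the spread, 0.009 higher after sCD40L, exact permutation p = 0.281), so the fit could hardly have lowered the change. It does not test quality differences that these measures miss. Genes of like brightness did not share the fall, as 0 of 10000 random lists matched on mean value had a median as low. Of these lists, which leave out the correlation between genes, 95% lay between -0.07 and 0.07. Loss of contaminating dendritic cells or monocytes would lower their markers, and the 4 markers more than 1 log2 unit above the brightest nonspecific control (CLEC7A, LILRA4, IL3RA and TCF4, of which B cells are known to express some) had a median change of 0.054 (SD 0.18), while the abundant monocyte transcripts S100A9 and LYZ lay at nonspecific levels, 5.35 and 4.83 in mock cells. Among the dendritic cell markers TCF4 (-0.30, lower in 6 of 6 donors) and the dimmer CD1C (-0.37) fell as much as the list, so a loss of such cells stays open, and no biological explanation was tested.

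Antisense transcripts tended to move with the genes they are named after, and over 630 such pairs the rank correlation of the changes was 0.27, against 0.08 over 15817 pairs of adjacent genes that do not overlap (1-sided permutation p = 0.0001, the smallest these permutations can give; pairs are not independent). Both members changed in 36 pairs, in one direction in 32, against 459 of 698 adjacent pairs (65.8%), as in FAS-AS1 (1.14) with FAS, IL21R-AS1 (0.71) with IL21R (0.56), FOXP1-AS1 (0.49) with FOXP1 (0.63) and SATB1-AS1 (-0.65) with SATB1 (-0.53). The mock mean of FAS-AS1 was not above the brightest nonspecific control, against which FAS-AS1 was at least 2.13-fold higher. The 4 opposing pairs were OTUD6B-AS1 (-0.42) with OTUD6B (0.81), NIFK-AS1 (-0.44) with NIFK (0.36), MRTFA-AS1 (0.33) with MRTFA (-0.39) and SLC60A1-AS1 (-0.25) with SLC60A1 (0.29), and the calls of SLC60A1, SLC60A1-AS1 and MRTFA-AS1 were lost in 8, 7 and 7 other settings. A second probe set of NIFK-AS1 (0.88) and one of MRTFA (0.26) rose, which would put those pairs in one direction. The reverse holds for FAM13A (-0.21) with FAM13A-AS1 (-0.48), which count as moving in one direction. FAM13A probe sets at 0.85 and 0.46 rose, while those at -0.51 and -0.66 fell. Shared control of a locus, or host signal in probe sets assigned to the antisense gene, could both give this, and the test does not separate them.

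On the 3 arrays with a lower brightness ceiling, the 20 genes brightest elsewhere were lower by a median of 1.83 log2 units, and the brightest control reached at most 13.9 against a median of 14.8 on the others. A lower ceiling as the cause of most calls is argued against, since 87.8% of the changed genes were still called without these arrays. The 20 brightest genes, which the ceiling lowered, were not tested separately. Why these arrays differ was not tested.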
